A study of Mus musculus with 2 samples.

How the data were processed

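Single-cell RNA sequencing was run on 2 libraries of mouse kidney cells, 1 from saline-treated and 1 from cisplatin-treated mice. Per the labels' protocols, kidneys of male C57BL6/J mice aged 10 to 12 weeks were taken 72 h after treatment (cisplatin at 20 mg/kg), with 10 kidneys per condition. The tissue was digested with collagenases and dispase, filtered, and passed through magnetic beads against CD31 (the endothelial protein Pecam1) and then against podoplanin, a pair of surface proteins that lymphatic endothelial cells carry together. Libraries were made with a droplet kit that tags the 3' end of each transcript with a unique molecular identifier (UMI).

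The authors deposited matrices of raw UMI counts per gene and barcode, with whole numbers and no normalization, for 32285 genes in each library. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.1 against mm10; per the file headers, the matrices carry the Cell Ranger version 4 mark, and the difference could not be resolved here. The matrices were unfiltered: 1001832 barcodes were listed for saline and 868686 for cisplatin, of which 204118 and 449347 held at least 1 UMI. Which barcodes the authors called cells is not given in the sources used here.

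A barcode was kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. Scrublet, run per library through scanpy, called 1 of 625 barcodes in saline and 2 of 1725 in cisplatin doublets. Those shares (0.16% and 0.116%) lay under the 0.5% set as the lowest share at which calls would be acted on, so no barcode was removed, and doublets remain an open source of mixed profiles. Both libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2: counts per cell scaled to 10000, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, no batch integration. The genes of all 19 response lists, mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes were left out of clustering. Clusters were named from marker lists of 22 classes; a name needed at least 3 markers at least 3-fold above the other cells, and clusters with the same name were joined into a class. Names are written as "-like", since no annotation of the cells by the authors was used here.

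For a class with at least 50 cells in each library, UMIs were summed over its cells per library and expressed as CPM (UMIs of a gene over all UMIs of the class, on a common scale). The ratio of cisplatin to saline has an exact (Clopper-Pearson) conditional binomial 95% interval, and shares of barcodes have exact (Clopper-Pearson) binomial 95% intervals. With 1 library per group there was no replicate, so no test was run and no p-value is given; all intervals cover counting error only. Log2 ratios had 0.5 UMI added per library. For each list, the median log2 ratio of members with at least 20 UMIs was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins (2000 random lists under the alternatives), and its interval came from 1000 Poisson draws of the counts. A member counted as higher or lower with a ratio of at least 1.5 either way and an interval that left out 1. Where a library held 0 UMIs of a gene, a fold was computed against a floor of 3 UMIs.

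The genes named were set by rule before the data were examined: the 8 highest and 8 lowest in the class by the interval bound nearest 1, given a bound beyond 1.5, and 2 to 4 members of each list farthest from 1 by the same bound (at most 3 were used), with Cd274, Ccl21a and Cdkn1a always. Cell type markers, non-coding gene models and genes for which free RNA would give most of the UMIs were left out of the ranking. Other genes named below were chosen after their values were seen, as markers or members of a list. The lists covered chemokines, leukocyte adhesion and trafficking, MHC class I and class II presentation, immune checkpoint and tolerance, interferon response, NF-kB and inflammatory signalling, p53 response, glycolysis, fatty acid oxidation, oxidative phosphorylation, hypoxia, oxidative stress and metallothioneins, the unfolded protein and integrated stress response, immediate early and heat shock genes, cell cycle, matrix and mesenchymal genes, lymphangiogenic signalling and valves, and tubule injury. Cxcl11, Ctgf, Cyr61 and Figf were not found under these names. Rps27l, a member of the p53 list, was at first dropped by the filter on ribosomal protein genes and was put back after first results had been seen.

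Free RNA, the transcripts that leak from broken cells into all droplets, was profiled from barcodes with 1 to 100 UMIs (3703779 UMIs in saline and 2140605 in cisplatin). Its share in a class was estimated from proximal tubule markers. Barcodes with at least 10 UMIs had a median of 37 UMIs in saline and 146 in cisplatin, so in the cisplatin library many droplets without a cell lay above the limit of 100 and the profile rests on its shallowest droplets.

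The ratio, interval and list steps were checked on simulated data drawn for the 8347 genes of the blood endothelial comparison. Counts were independent Poisson draws from the class's pooled profile, with no variation between cells, no shift of cell types and no linked list members. The rates below therefore hold for counting error only. In the data, 1 cell held 6.68% of the class's cisplatin UMIs. Intervals held the true ratio for 96.4% of unchanged genes, 96.7% of genes changed 2-fold and 97.8% of genes changed 4-fold. They left out 1 on the right side for 73.6% of the 2-fold and 96.6% of the 4-fold genes. Of random lists of 15 unchanged genes, 3.5% fell outside the middle 95% range, and 98% of lists with 8 of 15 genes at 2-fold lay above it.

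Alternative settings fixed in advance changed the UMI minimum, the mitochondrial limit, the resolution, the clustering genes, the gate, the scaling (TMM factors from edgeR 4.0.16 in R 4.3.3) and the subtraction of free RNA; further ones were chosen after seeing the data. All planned comparisons within lymphatic endothelial cells were left out because no such class was found. Gene positions are from GENCODE M21 on GRCm38 (the build also called mm10), matched by gene identifier for 32158 of 32285 genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scipy 1.17.1 and matplotlib 3.10.9.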

Results

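The study profiled cells that had passed CD31 and podoplanin bead enrichment, a selection meant to yield lymphatic endothelial cells, from the kidneys of mice given saline or the nephrotoxic chemotherapy drug cisplatin. The design asks how these cells differ 72 h after cisplatin. There was 1 library per treatment, so every comparison below sets 1 library against the other and has no replicate check. The saline library held 5879496 UMIs and the cisplatin library 19994105. Barcodes with at least 500 UMIs numbered 630 in saline and 3441 in cisplatin and carried 19.2% and 22.4% of all UMIs. After filtering, 625 saline barcodes (median 900 UMIs, 593 genes, 1.74% mitochondrial) and 1725 cisplatin barcodes (median 747 UMIs, 453 genes, 10.0% mitochondrial) were kept.

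**Figure D1:**
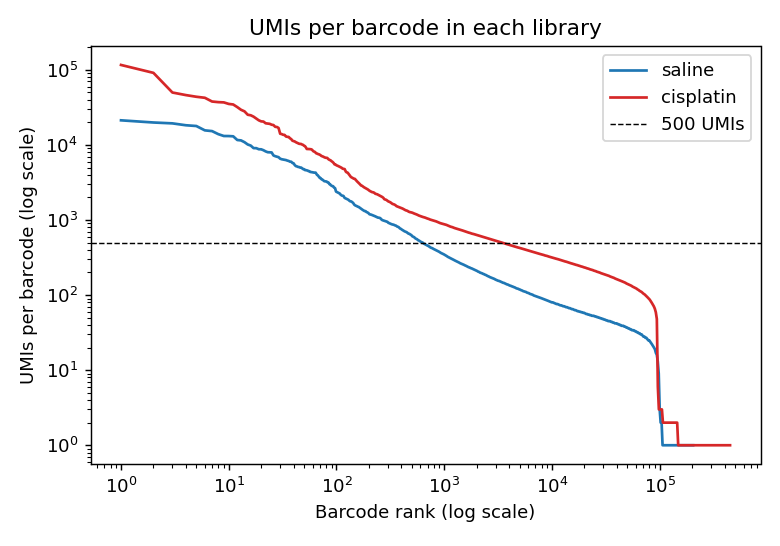
UMIs per barcode (log scale) against barcode rank (log scale), 1 line per library, with the minimum of 500 UMIs dashed. Neither line has a step between deep and shallow barcodes near the minimum, which 630 saline and 3441 cisplatin barcodes reached.

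No cluster of lymphatic endothelial-like cells was found in either library. That is 0 of 625 saline and 0 of 1725 cisplatin barcodes, which allows shares of up to 0.48% and 0.174% by a limit of 3 counts (exact upper bounds 0.588% and 0.214%). These limits hold for barcodes in a lymphatic cluster, and do not rule out single lymphatic cells placed in another class. Prox1, the transcription factor that sets lymphatic identity, had a UMI in 4 saline barcodes (0.64%, 0.175 to 1.63) and 11 cisplatin barcodes (0.638%, 0.319 to 1.14). In proximal tubule-like barcodes, which should lack it, the shares were 0.82% (median depth 695 UMIs) and 0.591% (771.5 UMIs), so a Prox1 UMI need not mark a lymphatic cell. These barcodes are themselves part of the kept ones, so the shares do not settle whether Prox1 lay above background. Lyve1, a hyaluronan receptor of lymphatic vessels, was seen in 1 barcode of each library, with 6 UMIs in the saline one, which lay in the blood endothelial-like class. Mmrn1 was seen in 0 and 1 barcodes, Pdpn (podoplanin) in 2 and 17, and the lymphatic chemokine Ccl21a in 3 and 6. By contrast, Pecam1 had a UMI in 49.9% of saline barcodes (45.9 to 53.9) and 14.0% of cisplatin barcodes (12.4 to 15.7). No kept barcode held UMIs of at least 2 of Prox1, Lyve1, Mmrn1, Reln and Ccl21a, and a gate on the lymphatic markers took 0 of these barcodes in both libraries; at a minimum of 300 UMIs and any mitochondrial share it took 0 in saline and 5 in cisplatin. With no lymphatic class, its expression, gene lists and subclusters could not be compared.

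Blood endothelial-like cells made up most of the saline library and a small part of the cisplatin library: 449 of 625 (71.8%, 68.1 to 75.3) against 147 of 1725 (8.52%, 7.25 to 9.94). Proximal tubule-like barcodes were 122 (19.5%, 16.5 to 22.8) against 1016 (58.9%, 56.5 to 61.2). Macrophage-like cells were 8 (1.28%, 0.554 to 2.51) against 108 (6.26%, 5.16 to 7.51), and collecting duct principal-like cells 4 (0.64%, 0.175 to 1.63) against 88 (5.1%, 4.11 to 6.25). The macrophage-like cluster is mixed: beside 9 macrophage markers it held 7 pericyte and smooth muscle markers, C1qa was seen in 60 of its 108 cisplatin cells, and a pericyte-like cluster of 2 saline and 13 cisplatin cells stood apart with at least 1000 UMIs. The collecting duct share depends on the clustering: in cisplatin it was 0.87% at resolution 2 and 0.174% by a marker gate, where that of macrophage-like cells was 3.59% and 3.01%. A cluster of shallow barcodes that stayed unnamed, led by the tubule injury gene Havcr1, held 42 (6.72%) and 366 (21.2%). Bead enrichment, the UMI minimum and the deeper cisplatin library can all set these shares. The proximal tubule-like barcodes carried tubule markers at 130% (saline) and 120% (cisplatin) of their level in free RNA, which leaves open how many of them are whole cells. Against that, Malat1 was 12.5% and 9.34% of their UMIs and 10.5% and 2.22% of free RNA, so in cisplatin they differ from the free RNA profile. The saline share of blood endothelial-like cells was 37.1% to 37.6% under 3 of the planned settings, in which large-vessel clusters lacked 3 markers and stayed unnamed.

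**Figure D2:**
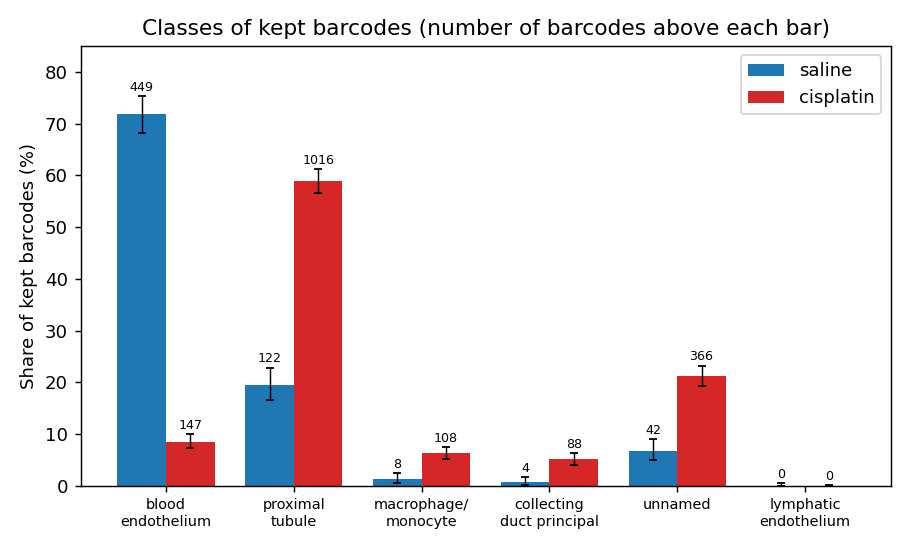
Share of kept barcodes (%) per class in the saline and cisplatin libraries, with exact 95% binomial intervals that cover counting error only and the number of barcodes above each bar. Blood endothelial-like cells were 71.8% of saline and 8.52% of cisplatin barcodes, and no barcode fell in the lymphatic class.

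Within blood endothelial-like cells, the genes of the p53 response, the program that follows DNA damage, were higher in the cisplatin library as a group. Of 18 measured members, 13 were higher, 0 were lower and 5 were neither; the median log2 ratio was 1.10 (0.79 to 1.31), at percentile 100 of the random lists. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, GRCm38), had 163 UMIs in saline and 484 in cisplatin, a 3.82-fold higher CPM (3.20 to 4.6). Trp53inp1 was 5.37-fold higher (3.41 to 8.76), Phlda3 3.61-fold (2.65 to 4.99), Bax, which promotes cell death, 2.19-fold (1.79 to 2.68), and Mdm2, which targets p53 for degradation, 2.27-fold (1.47 to 3.57). The median lay outside the middle 95% of random lists under all 19 alternative settings, but was 0.54 (0.32 to 0.98) when the 3 doublet calls were removed, a setting in which a cluster of 17 saline and 55 cisplatin cells of mixed glomerular and podocyte profile stood apart and the class held 433 and 96 cells. In the capillary-like cluster at resolution 2 (134 saline and 60 cisplatin cells) only 5 members were measured, 3 of them higher and 1, Plk2, lower. The median there was 0.84 at percentile 99.68, but its interval included 0 (-0.01 to 1.51) and the mean log2 ratio was -0.27. Podocyte markers inside the class had 174 UMIs in saline and 803 in cisplatin, a 5.94-fold higher CPM (5.04 to 7.04). Proximal tubule markers were 2.37-fold higher in the class (2.08 to 2.70) and macrophage markers lower (0.772, 0.632 to 0.941). Mesothelial markers (3 and 84 UMIs) and urothelial markers (1 and 115) were higher too, but only 1 and 2 cisplatin cells held at least 2 of them. Wt1, which is on both the podocyte and the mesothelial list, gave 2 and 53 of the mesothelial UMIs.

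The joint list of heat shock and immediate early genes had a lower median in the cisplatin library, carried by its heat shock members. Of 18 measured members 9 were lower, 3 were higher and 6 were neither, with a median log2 ratio of -0.59 (-0.96 to -0.44) at percentile 0.04. Hspa1a, an inducible HSP70 chaperone (chromosome 17, 34969190 to 34972156), had 374 UMIs in saline and 30 in cisplatin, a ratio of 0.103 (0.0687 to 0.15). The ratios were 0.139 (0.088 to 0.21) for its neighbour and near-copy Hspa1b, whose reads can be shared with it, and 0.302 (0.252 to 0.359) for the HSP90 gene Hsp90aa1. Of the heat shock members 6 of 7 were lower (median -1.51, -1.89 to -1.24). The immediate early members were not lower as a set (median -0.08, -0.24 to 0.42, percentile 42.1). They went both ways, with Fos, Jun and Egr1 lower and Junb, Ier3 and Zfp36 higher. With the mitochondrial limit at 10%, the median of the joint list was -0.38 at percentile 9.48.

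Glycolytic genes were higher in the cisplatin library as a group, by a smaller size: 4 of 13 were higher, 0 were lower and 9 were neither, with a median log2 ratio of 0.56 (0.36 to 0.73) at percentile 99.93. Pfkfb3, which makes an activator of glycolysis, was 2.94-fold higher (1.53 to 5.97), Gpi1 1.80-fold (1.38 to 2.37) and Gapdh 1.71-fold (1.44 to 2.02). The median was 0.22, at percentile 89.25, when each cell was thinned to 1000 UMIs, which left 237 saline and 90 cisplatin cells.

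**Figure D3:**
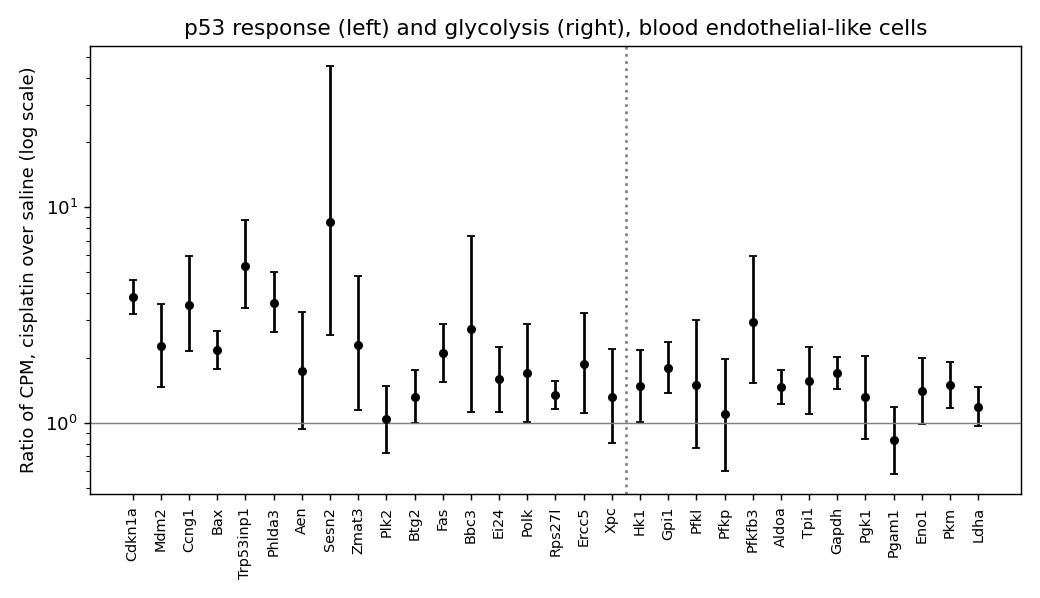
Ratio of CPM (log scale), cisplatin over saline, for each measured p53 response gene (left of the dotted line) and glycolysis gene (right) in blood endothelial-like cells, with exact 95% intervals that cover counting error only. Of the p53 genes 13 of 18 and of the glycolysis genes 4 of 13 were at least 1.5-fold higher with an interval above 1.

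The vessel types behind this class differed between the libraries. Cluster 2, led by capillary and glomerular endothelial genes such as Fabp4, Plvap and Ehd3, gave 24.8% of the class's UMIs in saline and 84.5% in cisplatin. Cluster 4, led by large-vessel genes such as Eln, Calca and Thbs2, gave 75.2% and 15.5%. The 3 lists above kept their direction inside each cluster alone. The p53 medians were 1.07 in cluster 2 and 0.62 in cluster 4. Those of glycolysis were 0.93 and 0.44, and those of the heat shock and immediate early list -0.71 and -1.11. Cluster 2 need not hold the same cells in both libraries. Inside it Ehd3 was 1.90-fold higher (1.56 to 2.33), while Fabp4 and Plvap had ratios of 0.29 and 0.706. At resolution 2 a mixed glomerular and podocyte cluster of 7 saline and 56 cisplatin cells stood apart. The cluster 2 medians therefore do not exclude a shift of cell types within it. Few members passed on their own in cluster 4, which held 22 cisplatin cells: 3 of 13 p53 genes were higher (Btg2, Fas and Ei24, none of them named above) and 2 of 11 glycolysis genes (Tpi1 and Eno1), against 9 of 17 and 5 of 13 in cluster 2. The estimated share of free RNA in the class was 2.72% in saline and 8.55% in cisplatin, and the mitochondrial share 2.17% and 5.62%. The share of UMIs from the nuclear RNA Malat1 was 4.89% and 3.26%. Its ratio was 0.36 in cluster 2, 0.994 in cluster 4 and 0.165 (0.155 to 0.176) in the capillary-like cluster at resolution 2. In that last cluster Cdh5 had a ratio of 0.274 (0.141 to 0.489) and the tubule gene Kap 1.90 (1.19 to 3.02). Its saline and cisplatin barcodes can therefore differ in quality. This limit holds for every value given from that cluster.

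**Figure D4:**
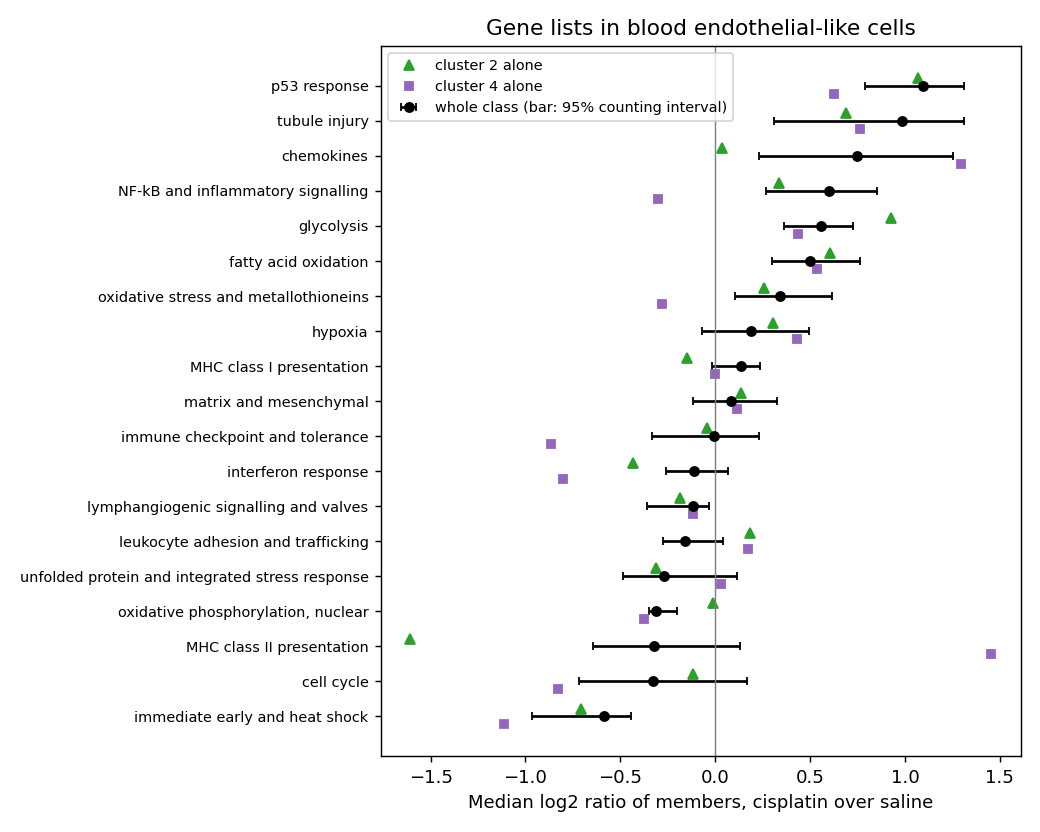
Median log2 ratio, cisplatin over saline, of the measured members of each list in blood endothelial-like cells (black, with 95% counting intervals), in cluster 2 alone (green) and in cluster 4 alone (purple). The p53 response median was 1.10 in the class, 1.07 in cluster 2 and 0.62 in cluster 4.

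A further 4 lists lay above the middle 95% of random lists in the class but changed sign under at least 1 alternative. Fatty acid oxidation had 7 of 15 members higher and 1 lower (median 0.50, 0.30 to 0.76, percentile 99.68). Acaa2 was 2.68-fold higher (1.65 to 4.45) and Slc25a20 2.81-fold higher (1.33 to 6.36). The fatty acid carrier Fabp5 had a ratio of 0.54 (0.402 to 0.718) in the class. Its ratio was 0.166 (0.123 to 0.222) in cluster 2 and 1.04 (0.113 to 4.67) in cluster 4. NF-kB and inflammatory signalling had 5 of 15 members higher and 2 lower (median 0.60, 0.27 to 0.85, percentile 99.45). Socs3, a feedback inhibitor of cytokine signalling, was 16.7-fold higher (6.16 to 63.7), while Ptgs2 (cyclooxygenase-2) had 26 UMIs in saline and 1 in cisplatin. All 26 saline UMIs of Ptgs2 lay in cluster 4, the smaller part of the class in cisplatin. In cluster 4 cisplatin had 0 (upper bound of the ratio 0.951). In the oxidative stress and metallothionein list 4 of 14 were higher and 2 lower (median 0.34, 0.11 to 0.62, percentile 98.95). With free RNA subtracted the median was 0.12 (-0.07 to 0.33) at percentile 77.2, inside the range, and Gpx3 passed from higher to lower, so this list is not read as a difference of the cells. The metal-binding proteins Mt1 (16.3-fold, 10.6 to 26.5) and Mt2 (33.2-fold, 12.6 to 124.03) were higher and Gpx1 was lower (0.523, 0.441 to 0.618), though Gpx1 turned direction with the mitochondrial limit at 10%. Of the tubule injury list 5 of 9 were higher and 0 lower (median 0.99, 0.31 to 1.31, percentile 99.97), with Spp1, Lcn2 and Krt18 farthest from 1; this median was 0.04 without cells that held a podocyte or urothelial UMI.

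The other 12 lists lay inside the middle 95% of random lists. For interferon response 3 of 27 members were higher and 4 lower (median -0.11, percentile 20.81), with Ifit3 2.33-fold higher (1.61 to 3.40) and Ifi27l2a at 0.418 (0.349 to 0.498), though 0.783 (0.587 to 1.05) in cluster 2 and turned in direction at resolution 2 and at 10% mitochondrial. Each cluster alone lay below the range: in cluster 2, 1 was higher and 7 lower (median -0.43, percentile 0.425), and in cluster 4, 0 were higher and 4 lower (median -0.80, percentile 0). At resolution 2 a cluster of mixed glomerular and podocyte profile (7 saline and 56 cisplatin cells) stood apart, so the cells in cluster 2 can differ between libraries. In that setting the list lay inside the range (-0.05, percentile 87.3). So it did in the capillary-like cluster alone (-0.59, percentile 7.4) and with doublet calls removed (-0.15, percentile 44.1). The interferon list lay above the range with list genes allowed in clustering (10 higher and 1 lower, median 0.44, percentile 99.95). With at least 1000 UMIs it lay above the range too (6 higher and 0 lower, median 0.23, percentile 97.7). Its direction therefore depends on the setting. MHC class I presentation had 3 of 19 higher and 2 lower (median 0.14, percentile 96.80); H2-Q7 (2.60-fold, 2.13 to 3.18), H2-Q6 (2.28-fold, 1.78 to 2.93) and H2-T23 (1.86-fold, 1.56 to 2.22) were higher, and the near-identical H2-Q genes can share reads. H2-Q7 turned direction at resolution 2. None of 5 measured MHC class II genes was higher or lower in the class (median -0.32, percentile 9.96), but the clusters taken alone went opposite ways. In cluster 2 all 4 measured members, among them Cd74 and H2-Aa, were lower (median -1.61, -2.16 to -1.17, percentile 0), and in cluster 4 Cd74 and H2-Eb1 of 3 were higher (median 1.46, 0.54 to 2.07, percentile 99.9). With doublet calls removed, 0 of 4 were higher or lower (median 0.22, percentile 79.4). By the marker gate 4 of 5 were lower (-0.78, percentile 0.25), as were 2 of 3 with at least 1000 UMIs and 2 of 4 at 10% mitochondrial. For leukocyte adhesion 4 of 15 were higher and 0 lower (median -0.16, percentile 24.93), among them Icam1 (3.31-fold, 1.97 to 5.77), Vcam1 (2.04-fold, 1.40 to 2.99) and Alcam (3.63-fold, 1.78 to 8), receptors that bind leukocytes; Alcam had a ratio of 0.638 without cells that held a podocyte or urothelial UMI. Chemokines had 4 measured members (median 0.75, percentile 96.45): Cxcl16 was 3.54-fold higher (1.52 to 9.20) and Cxcl12 had a ratio of 0.226 (0.17 to 0.296) in the class, but 0.757 (0.364 to 1.66) in cluster 2 and 0.701 (0.49 to 0.978) in cluster 4. Of 8 checkpoint and tolerance genes 0 were higher and 1 lower (median -0.01, percentile 46.92); Cd274, which encodes PD-L1, had 23 and 19 UMIs and a ratio of 1.06 (0.548 to 2.04), so no difference was detectable at this depth. Ccl21a had 1 and 0 UMIs in the class.

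Hypoxia genes were higher for 2 of 10 (median 0.19, percentile 82.10), namely Vegfa (5.59-fold, 3.85 to 8.33; 2.68-fold without cells that held a podocyte or urothelial UMI) and Pdk1 (4.51-fold, 2.00 to 11.4). Nuclear oxidative phosphorylation genes had 2 of 28 higher and 1 lower (median -0.31, percentile 5.65), with Atp5b at 1.79-fold (1.51 to 2.12) and Atp5e at 0.577 (0.509 to 0.652). The unfolded protein list had 1 of 10 higher and 2 lower (median -0.27, percentile 10.73), with Hsp90b1 at 0.621 (0.543 to 0.71). Cell cycle genes had 1 of 7 higher and 2 lower (median -0.33, percentile 7.82), and lymphangiogenic and valve genes 3 of 19 higher and 5 lower (median -0.12, percentile 38.98). In this last group Nr2f2, a venous transcription factor, was 3.36-fold higher (2.27 to 5.09), and Klf4, a gene induced by flow, had a ratio of 0.426 (0.367 to 0.493); both turned direction in 1 of the clusters taken alone. Matrix and mesenchymal genes had 6 of 18 higher, among them Col1a2, Tagln and Acta2, and 6 lower (median 0.09, percentile 83.01). Markers of pericytes and smooth muscle (5.22-fold, 3.17 to 8.99) and of fibroblasts (4.81-fold, 2.87 to 8.46), which include these 3 genes, were higher in the class too, and the list median was -0.66 at percentile 0.25 with at least 100 UMIs per gene.

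Ranked by size over all genes, the 8 highest in the cisplatin library were Spp1, Plat, Lpl, Clic3, Tcf21, Wfdc2, Fxyd3 and Mt2. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), had 2 and 290 UMIs, a ratio of 187 (51.2 to 1549). Without cells that held a podocyte or urothelial UMI it had 2 and 88 UMIs and a ratio of 77.2 (20.8 to 648). The ratio of Wfdc2 went from 50.9 to 14.9 in the same setting. Spp1 stood at 1567 CPM in the free RNA of the cisplatin library, against 388 CPM in the class. Free RNA, estimated at 8.55% of the class's cisplatin UMIs, can therefore give part of the 290 and of the 88 UMIs. How much of the 88 it gives was not computed. Plat, the tissue plasminogen activator (chromosome 8, 22757727 to 22782844), had 110 and 1824 UMIs and was 21.4-fold higher (17.6 to 26.1), and the lipoprotein lipase gene Lpl was 24.4-fold higher (16.3 to 38); within cluster 2 alone their ratios were 10.6 and 11.1. In the capillary-like cluster at resolution 2, Plat had 48 and 24 UMIs and a ratio of 1.05 (0.616 to 1.75), that is, no detectable difference, while Lpl was 4.42-fold higher (1.99 to 10.5). Clic3, Tcf21 and Fxyd3 came from 9, 3 and 1 cisplatin cells, and without cells that held a podocyte or urothelial UMI Clic3 had a ratio of 1.17. The urothelial keratin Krt15 had 99 UMIs, all in 1 cisplatin cell. The 8 lowest were Calca, Hspa1a, Ptn, Thbs2, Bmp2, Cacng4, Tgfb2 and Hspa1b. Calca, Thbs2, Bmp2 and Tgfb2 are among the leading genes that define cluster 4, so their class ratios are not read as results. Within cluster 2 and cluster 4 alone the ratios were 0.0131 and 0.437 for Calca, 0.355 and 0.416 for Tgfb2, 1.08 and 0.195 for Thbs2, and 1.14 and 0.229 for Bmp2. Cluster 4 also held 79 of the 80 saline UMIs of Ptn and all 27 of Cacng4, so their class ratios carry the same limit. In cluster 4 cisplatin had 0 UMIs of both (upper bounds of the ratio 0.298 and 0.913). Another scaling, by the median of ratios, moved all log2 ratios by -0.11.

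In the other class with enough barcodes in both libraries, the proximal tubule-like one, 3 lists lay outside the middle 95% of random lists. The p53 response had 10 of 19 members higher and 0 lower (median 1.71, 1.32 to 2.98, percentile 100), with Cdkn1a at 1 and 198 UMIs, a ratio of 20.3 (3.60 to 805). Tubule injury had 5 of 13 higher and 0 lower (median 1.77, 1.54 to 4.66, percentile 99.99), with Spp1 7.70-fold higher (4.39 to 15.0). The immediate early and heat shock list had 4 of 17 higher and 3 lower (median 0.73, -0.08 to 1.58, percentile 99.55). With members at 0 UMIs in saline set to the floor, these medians were 1.49, 1.14 and 0.38. Of the remaining lists 15 lay inside the range and cell cycle had too few measured members. The saline sum for this class was 98398 UMIs, and how much of the class is free RNA is not known. Its mitochondrial share was 3.73% in saline and 10.7% in cisplatin.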

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

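The subtraction of free RNA was planned; the other tests in this part, and the bound set for the subtraction, were chosen after the related results had been seen.

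The immediate early and heat shock list had a median log2 ratio of -0.59 in blood endothelial-like cells and 0.73 in proximal tubule-like barcodes, opposite directions under the same contrast; the difference was not tested, and the interval of the second median includes 0. Split into its parts, the heat shock members were lower in both classes (medians -1.51 and -0.81), whereas the immediate early members had medians of -0.08 and 1.29. A difference in handling between the libraries would move free RNA too: there the heat shock members had a median of -0.91, as that explanation needs, while the immediate early members had 0.79, which decides nothing, since they were not lower in the blood endothelial-like class. For the heat shock genes, handling may therefore account for the lower level, and a response to cisplatin stays equally open because each treatment is 1 library.

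Free RNA, which the comparisons of cells do not use, held a strong p53 signal in the cisplatin library against the saline control, with a median log2 ratio of 1.62 over 24 members, 21 of them higher. Free RNA from injured tubules may thus be asked to explain the p53 list in blood endothelial-like cells, but with the estimated share subtracted that median was 1.02 (0.76 to 1.27), against 1.10 before. A shift between the capillary-like and large-vessel clusters is argued against by the lower of the 2 medians within clusters, 0.62 (0.26 to 1.07), though only 3 of 13 members were higher there by themselves. Glomerular cells mixed with podocytes could give part of the size: the median was 0.54 (0.32 to 0.98) once the mixed cluster was split off and 0.90 (0.70 to 1.28) without cells that held podocyte or urothelial UMIs, and these values do not decide it. A response of endothelial cells to cisplatin remains open as a hypothesis, and with 1 library per treatment it cannot be told apart from a library difference.

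Tubule injury genes stood out in free RNA, with a median log2 ratio of 1.90 and 13 of 15 members higher. Havcr1, which encodes the injury marker KIM-1, had 1 UMI in saline and 118 in cisplatin, a ratio of 204 (35.9 to 8132). Lcn2, which encodes the injury marker NGAL, had 6 and 342 UMIs, a ratio of 98.6 (44.8 to 271).

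Barcodes with at least 500 UMIs but over 20% mitochondrial UMIs, which were not analysed as cells, made up 49.8% (48.1 to 51.4) of such barcodes in the cisplatin library and 0.476% (0.0983 to 1.39) in the saline library. Free RNA was 30.6% mitochondrial in cisplatin and 3.84% in saline.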

How the results depend on the processing

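All values in this part are log2 ratios or list medians in blood endothelial-like cells, or shares of kept barcodes. The settings set in advance for lymphatic endothelial cells gave no value, since no setting yielded such a class, and keeping the doublet calls equalled the main setting. For list and gene values in blood endothelial-like cells only TMM scaling and free RNA subtraction were planned; all other settings, and the removal of doublet calls, were chosen after seeing the data. No paired analysis was possible because each group has 1 library. The p53 list lay outside the middle 95% of random lists under all 19 settings (0.54 to 1.18), glycolysis under 18 (0.22 to 1.04), and the immediate early and heat shock list under 15 (-1.11 to -0.38), each with its direction kept. Fatty acid oxidation did so under 15, tubule injury under 13, oxidative stress under 9 and NF-kB under 8 of 19. Of the lists inside that range, MHC class I lay outside it under 7 settings, interferon response under 5 (-0.80 to 0.44 over all settings), chemokines under 5 of 12 (-0.27 to 1.72), MHC class II under 5 of 15 (-1.61 to 1.46) and matrix and mesenchymal genes under 4 (-0.95 to 0.93); hypoxia, leukocyte adhesion, checkpoint and cell cycle did so under 1 each. TMM and free RNA subtraction turned none of the 7 lists, but subtraction put oxidative stress inside the range (0.12, percentile 77.2). The class holds 147 cisplatin cells. The cause of the moves below was not tested, except where fewer cells or unnamed clusters are stated.

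Blood endothelial-like shares in saline and cisplatin were 37.6% and 10.8% with at least 1000 UMIs, 37.2% and 7.19% with at most 10% mitochondrial UMIs, and 37.1% and 3.71% at resolution 2, where large-vessel clusters stayed unnamed. They were 66.9% and 5.33% with list genes allowed in clustering. In cisplatin alone the share was 10.6% by the marker gate and 5.57% with doublet calls removed. Other classes moved too. In cisplatin, collecting duct principal-like cells were 2.55% with at least 1000 UMIs, 0.87% at resolution 2 and 0.174% by the gate, and no cluster had this name at 10% mitochondrial (a similar one was named parietal epithelium and thin limb) or with list genes allowed (unnamed). Macrophage-like cells were 8.63%, 3.59% and 3.01% in the same 3 settings, and proximal tubule-like ones 46.4% at resolution 2 and 72.1% by the gate.

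For p53, the median was 0.54 with doublet calls removed, 0.62 in cluster 4, 0.72 as a mean over cells and 0.78 with list genes allowed. Glycolysis was 0.22 in thinned cells, 0.74 in the gate, 0.86 as a mean over cells, 0.91 in the capillary-like cluster at resolution 2, 0.93 in cluster 2 and 1.04 at 10% mitochondrial. The immediate early and heat shock list was -1.11 in cluster 4 and -0.38 at 10% mitochondrial. NF-kB turned to -0.50 at resolution 2, -0.24 in its capillary-like cluster, -0.30 in cluster 4 and -0.28 with doublet calls removed, and was 0.26 as a mean over cells and 0.0067 with at least 100 UMIs per gene. Fatty acid oxidation turned to -0.090 at resolution 2 and -0.76 in its capillary-like cluster, and was 0.10 in thinned cells. Oxidative stress turned to -0.10 and -0.29 in the same settings and -0.28 in cluster 4. Tubule injury turned to -0.58 in thinned cells and -0.0012 with at least 100 UMIs, and was 1.72 with no minimum, 0.041 without podocyte or urothelial cells and 0.036 when Spp1-bearing cells were left out too.

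Single genes also turned. Some genes with few UMIs crossed a ratio of 1 as well and are not listed below. Examples are Bmp2 (1 and 3 UMIs) and Ptn (1 and 4) in cluster 2, and Alcam (11 and 4) without podocyte or urothelial cells. At resolution 2 these were H2-Q7 (-0.49), Ifi27l2a (0.17), Ndrg1 (0.39), Xbp1 (-0.86), S100a4 (0.10) and Kdr (-0.83), and in its capillary-like cluster H2-Q7 (-0.49), Ndrg1 (0.071), Hspa5 (-0.42) and Kdr (-0.72). With at least 1000 UMIs they were Lgals1 (0.70), Ndrg1 (0.035) and Kdr (-0.55). At 10% mitochondrial they were Ifi27l2a (0.22), Ndrg1 (0.36), Gpx1 (0.17) and Kdr (-1.27). In cluster 2 they were Thbs2 (0.11), Lgals1 (0.11), Kdr (-0.30) and Klf4 (0.10), and in cluster 4 H2-Q7 (-0.54), Nr2f2 (-1.92) and Kdr (-1.53). With doublet calls removed they were H2-Q7 (-0.083), Xbp1 (-0.24), Nr2f2 (-0.22) and Kdr (-0.39). In thinned cells they were Lgals1 (0.78) and Hspa5 (-0.025). As a mean over cells they were Lgals1 (0.92), Ndrg1 (0.068), Xbp1 (-0.20), Hspa5 (-0.0095), Kdr (-0.0053) and Krt18 (-0.065). Without podocyte, urothelial and Spp1-bearing cells they were H2-Q7 (-0.039), H2-Q6 (-0.11), Xbp1 (-0.23) and Hspa5 (-0.19). Of 838 gene values under alternatives, 548 stayed within the main counting interval, 250 left it and 40 turned.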

Other observations

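The search of barcodes of any depth for lymphatic genes was set before its result was seen; the other test in this part was chosen after.

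In the cisplatin library, 88 collecting duct principal-like cells, too few in saline (4) for a comparison, held Lcn2 with 1792 UMIs in 27 cells and Cdkn1a with 362 UMIs in 32 cells, a level of 660 CPM (594 to 732). The estimated share of free RNA in this class was 7.15%. The cluster is mixed: beside 6 collecting duct markers it held 5 of the loop of Henle and distal tubule. Aqp2 was seen in 22 of the 88 cells, so the cells with Lcn2 or Cdkn1a need not be collecting duct cells. Both genes were picked after their values were seen, Lcn2 is among the leading genes of the cluster, and no list was run in this class.

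Among other lists in free RNA, chemokines were higher in the cisplatin library (median log2 ratio 0.99, 0.73 to 1.62), with 7 of 11 measured members higher. NF-kB and inflammatory signalling had a median of 0.79 with 9 of 16 higher, and oxidative phosphorylation 0.58 with 13 of 28 higher. The lymphangiogenic and valve list had a median of -0.59 (-0.73 to -0.44) at percentile 0.45. Malat1 was 10.5% of free RNA in saline and 2.22% in cisplatin.

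No lymphatic endothelial cluster was found although the enrichment was meant to yield these cells. Loss to the UMI and mitochondrial limits was looked for in barcodes with at least 300 UMIs: of 1196 saline and 11432 cisplatin barcodes at any mitochondrial share, 0 and 2 held at least 2 of the 5 genes Prox1, Lyve1, Mmrn1, Reln and Ccl21a. The wider marker gate took 0 and 5 of the same barcodes. Over all barcodes of any depth the number was again 0 in saline and 2 in cisplatin, from 151 and 255 UMIs of these genes in all. Neither search excludes lymphatic cells lost to the limits or too shallow to be kept, since the rate at which such a cell shows 2 of the genes was not measured, and this cannot be told apart from their absence. No biological explanation was tested, and how the authors chose their cells is not known here.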
